A study of Mus musculus with 2 samples.

How the data were processed

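H3K27me3 was measured by chromatin immunoprecipitation and sequencing in liver of B6NCrl mouse embryos at embryonic day 12.5, in 2 biological replicates of 1 group. Per the labels, replicate 1 came from a pool of 120 embryos and replicate 2 from a pool of 88, both sexes together, and the size range is given as 300 to 500. The group and the replicate numbers were taken from the sample labels. The deposited data used here are 4 peak lists on mm10, the build also called GRCm38: 1 for each replicate, 1 from both replicates pooled, and 1 of replicated peaks. Per the deposited notes, the list of replicate 1 derives from its filtered alignments and 1 further file, the lists of replicate 2 and of both replicates pooled derive from alignments and 2 further files, and the replicated list derives from the other 3 lists. The role of the further files, the aligner, the peak caller, their versions and thresholds are not given in the sources used here.

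Each peak in the deposited lists carries a signal value from the authors' peak caller, a measure of its enrichment. What the signal is relative to is not stated, so it is called a signal value and not a fold enrichment, which had been assumed before the data were examined. It was used within a list, to describe and rank peaks and, in the closing tests, to compare medians between sets of genes or chromosomes. Between the replicates' lists only the order of the signal values of overlapping peaks was compared. The lists also give, by the authors, −log10 of a p-value and −log10 of a q-value per peak. The smallest −log10 p was 2.01 in replicate 1, 2.01 in replicate 2 and 2.00 in the pooled list, and −log10 q was 2 or more for 74.2%, 81.6% and 85.5% of these peaks and for 98.6% of the replicated peaks. Since peaks were called separately per replicate and once on the pooled reads, a difference in reads between the replicates changes the number, length and strength of their peaks. The depth per sample is unknown because a peak list keeps no read counts, so no interval that needs reads is given. A caller of narrow peaks also splits broad regions of this mark into many short peaks, which is why bases and joined domains are given beside peak counts.

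All 73360 replicated peaks were also peaks of the pooled list. All 50637 pooled peaks that overlapped a peak in each replicate by at least 50% of either peak were in the replicated list, where they made up 69.0%, and the other 22723 met that overlap in only 1 replicate or, for 1012 of them, in neither. The rule that admitted these is not given in the sources used here.

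Peaks on the 21 assembled chromosomes were used. Gene positions came from GENCODE release M21 on GRCm38, and the sequence from the GRCm38.p6 reference. Exonic, intronic and outside refer to protein-coding genes. A gene's 5' end was the most upstream annotated start, a promoter was 1 kb on either side of it, and a gene was marked where a replicated peak overlapped the promoter by at least 1 bp. The covered share of a gene is the percent of the 5 kb centred on the 5' end that lies in peaks; it was computed for each replicate's own list, and its mean ± SD is over the 2 replicates. Signal values of a gene are the highest among peaks overlapping its promoter. Domains were replicated peaks joined where they lay 3 kb or less apart. CpG island class meant an observed to expected CpG ratio of 0.6 or more and a GC fraction of 0.5 or more in the 1 kb around the 5' end. Coordinates are given from 1.

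Replicate overlap and genomic location were compared with 100 random placements of the peaks within their own chromosomes, one-sided for overlap and two-sided for location. The gene lists were 18 lists named gene by gene, with 552 of 555 members found among the protein-coding genes, and 6 families taken by symbol. Ahsp was not found by that name, and H19 and Hand2os1 are not protein-coding. Of the genes in the lists, 16 belong to more than 1 list, and they count in each. Marking was tested with two-sided Fisher's exact tests against all other protein-coding genes and adjusted by the Benjamini-Hochberg method over the 24 lists at a threshold of 0.05. Each list was also set against 10000 random lists matched on CpG decile. CpG ratios were compared by a permutation test with 100000 resamples, and chromosome X by its rank among 20 chromosomes. Proportions carry 95% Wilson intervals, which cover counting error over genes only. For each list the genes named are the 4 marked members with the largest covered share in the replicated list, ties broken by signal value, or all marked members where there are 5 or fewer; for the hepatoblast, erythroid and housekeeping lists the 4 unmarked members that come earliest in the list are named too. The 10 longest domains and the 10 genes with the highest signal values were also named by rule. The design, lists, rules and alternatives were fixed before the data were examined. Alternatives were a stricter q, the pooled list, each replicate alone, a wider promoter, any transcript start, a required coverage of 25%, one member per locus within 100 kb, other overlap rules, rotated peaks and other joining distances; marking in both replicates' own lists was added after seeing the data.

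The list test was tested on simulated data with 21911 genes and 100 simulations: of 12 lists raised from 30% to 70% marked, 94.75% were called, and of 7 lists not raised, 6.14% were called. Each simulated gene was drawn independently, whereas members of a real list can share a domain, and no smaller rise was simulated. The raised lists also lifted the share among the other genes against which the lists not raised were tested. These rates therefore need not hold for clustered lists or smaller differences. The overlap step was run on replicate 1 against a copy with 59.8% of its peaks kept in place, and it returned that share exactly. Each kept peak overlaps itself, so this checks the counting only and not overlap between separately called peaks. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Reads were not analysed here.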

Results

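H3K27me3, the trimethylation of lysine 27 on histone H3 that Polycomb repressive complex 2 deposits at silenced genes, was mapped by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at embryonic day 12.5. At this stage the liver holds hepatoblasts, the bipotent precursors of hepatocytes and of bile duct cells, and it is also the main site of blood formation. The series had 1 group with 2 biological replicates. Replicate 1 was a pool of 120 embryos and replicate 2 a pool of 88 embryos, both of mixed sex, so each value is an average over many embryos and over all cell types of the organ. The design has no second tissue, stage or treatment, and the comparisons it allows are those between the replicates and those between genes or regions within the liver. The replicate 1 list held 106222 peaks covering 59.1 Mb, and the replicate 2 list held 153706 peaks covering 89.2 Mb. The authors' replicated list, on which the values below rest unless another list is named, held 73360 peaks covering 80.9 Mb, or 2.97% of the assembled chromosomes. The number of reads behind each list is unknown, so the depth cannot be set beside these counts, and the marked shares carry intervals that cover counting error over genes alone.

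The replicates agreed more at strong peaks than at weak ones, and more of replicate 1 lay in replicate 2 than the reverse. Of the replicate 1 peaks, 67.5% overlapped a replicate 2 peak by at least 1 bp, against 6.85% when the replicate 2 peaks were placed at random within their chromosomes. In the other direction 38.3% of replicate 2 peaks overlapped a replicate 1 peak, against 4.80% by random placement. Both shares exceeded all 100 placements (one-sided permutation p = 0.0099, the smallest that number allows). Measured in bases, 77.0% of the replicate 1 sequence lay in replicate 2 peaks and 51.0% of the replicate 2 sequence lay in replicate 1 peaks. Replicate 2 had 1.45 times as many peaks and 1.51 times as many covered bases. When each list was ordered by the authors' −log10 p, 92.8% of the strongest 25% of replicate 1 peaks and 73.2% of those of replicate 2 were overlapped in the other replicate, and 50.5% and 20.1% of the weakest 25%. The strongest 25% were also longer, with median lengths of 615 and 653 bp against 233 and 232 bp in the weakest 25%. Longer peaks overlap more easily at 1 bp, and these parts were not compared with random placement. The signal value of overlapping peaks was ordered only partly alike (Spearman rho 0.47 across 71662 peaks). The share of the 5 kb around a gene's 5' end covered by peaks was ordered closely alike (rho 0.96 across the 7668 genes marked in either replicate). The signal was compared only at overlapping peaks and the covered share also at genes marked in 1 replicate, so the values are not like for like. These correlations are across peaks or genes, which are not independent replicates.

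**Figure D1:**
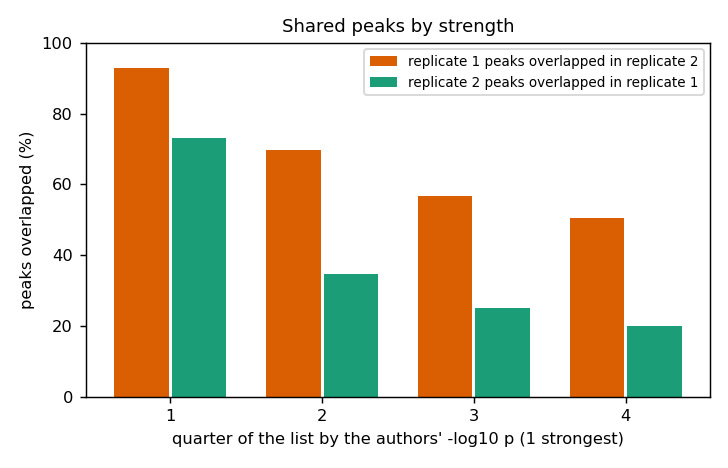
Share of each replicate's peaks (y axis, %) overlapped by at least 1 bp in the other replicate, in 4 equal parts of its list ordered by the authors' −log10 p (x axis, 1 strongest). Orange bars are replicate 1 peaks, falling from 92.8% to 50.5%, and green bars are replicate 2 peaks, falling from 73.2% to 20.1%. Stronger peaks were also longer, and the parts were not compared with random placement.

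H3K27me3 was concentrated at the 5' ends of genes, where its peaks were also longer. Sequence within 1 kb of a protein-coding 5' end held 11.7% of the bases in replicated peaks against 1.69% under random placement, a 6.93-fold excess, and 10.5% of the peaks against 2.55%. Intergenic sequence held 44.4% of the bases against 58.6%. Each of these shares lay outside all 100 placements (two-sided permutation p = 0.0198, the smallest possible). Promoter peaks had a median length of 2111 bp and a median signal value of 5.0, and the other peaks a median length of 551 bp and a median signal value of 2.79. A peak counted as a promoter peak where it overlapped a promoter, so longer peaks were likelier to be counted there. The lengths were not compared with random placement. Of the bases in replicated peaks, 11.2% were exonic, 39.4% intronic and 49.4% outside protein-coding genes. In the replicate 2 list alone the promoter share of peaks was 6.54%.

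A replicated peak overlapped the promoter, taken as 1 kb on either side of the annotated 5' end, of 6515 of 21911 protein-coding genes (29.7%, 95% Wilson interval 29.1 to 30.3). The lists of the replicates alone marked 6494 and 7307 genes, and 6133 genes were marked in both, which is 80.0% of those marked in either. All gene lists below were tested against all other protein-coding genes, of which 29.6% to 31.3% were marked, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 24 lists. Genes are not independent replicates, so these tests describe the gene lists in these pools of embryos and not the variation between pools.

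Genes that specify other organs carried the mark in nearly every case. All 39 Hox genes tested, which set position along the body axis, were marked (adjusted p = 1.59e-20 by Fisher's exact test), as were all 40 transcription factors of the nervous system (adjusted p = 6.26e-21) and all 20 of other endoderm organs such as gut, pancreas and lung (adjusted p = 8.58e-11). Of 40 transcription factors of heart, muscle, limb and other mesoderm, 35 were marked (adjusted p = 1.66e-13 by Fisher's exact test). Hox genes lie in 4 clusters, and with 1 member per locus within 100 kb the Hox list was 4 of 4 marked (adjusted p = 0.0109 by Fisher's exact test). Each replicate alone also marked every member of the Hox, neural and other endoderm lists. At Olig2, a factor of oligodendrocyte and motor neuron precursors on chromosome 16 with its 5' end at 91225457, peaks covered 100% of the surrounding 5 kb in both replicates, and the highest signal value was 29.2 in the replicated list. Dmrta2 and Nkx6-2 were also fully covered in both replicates, and Sox1 was covered to 98.3% ± 2.4 (SD, n = 2). In the mesoderm list, Foxc2, Hand2 and Pitx1, a hindlimb factor, were fully covered in both replicates and Six1 to 97.8% ± 3.1 (SD, n = 2). The unmarked members were the muscle factors Myf5, Myf6 and Myog and the paraxial mesoderm factors Tbx6 and Msgn1, named here after their values were seen. Among factors of other endoderm organs, the intestinal regulator Cdx2, the gut factor Nkx2-3, the thyroid factor Foxe1 and the pancreatic and motor neuron factor Mnx1 were fully covered in both replicates. That list also holds Foxa1, a factor that the liver expresses too.

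**Figure D2:**
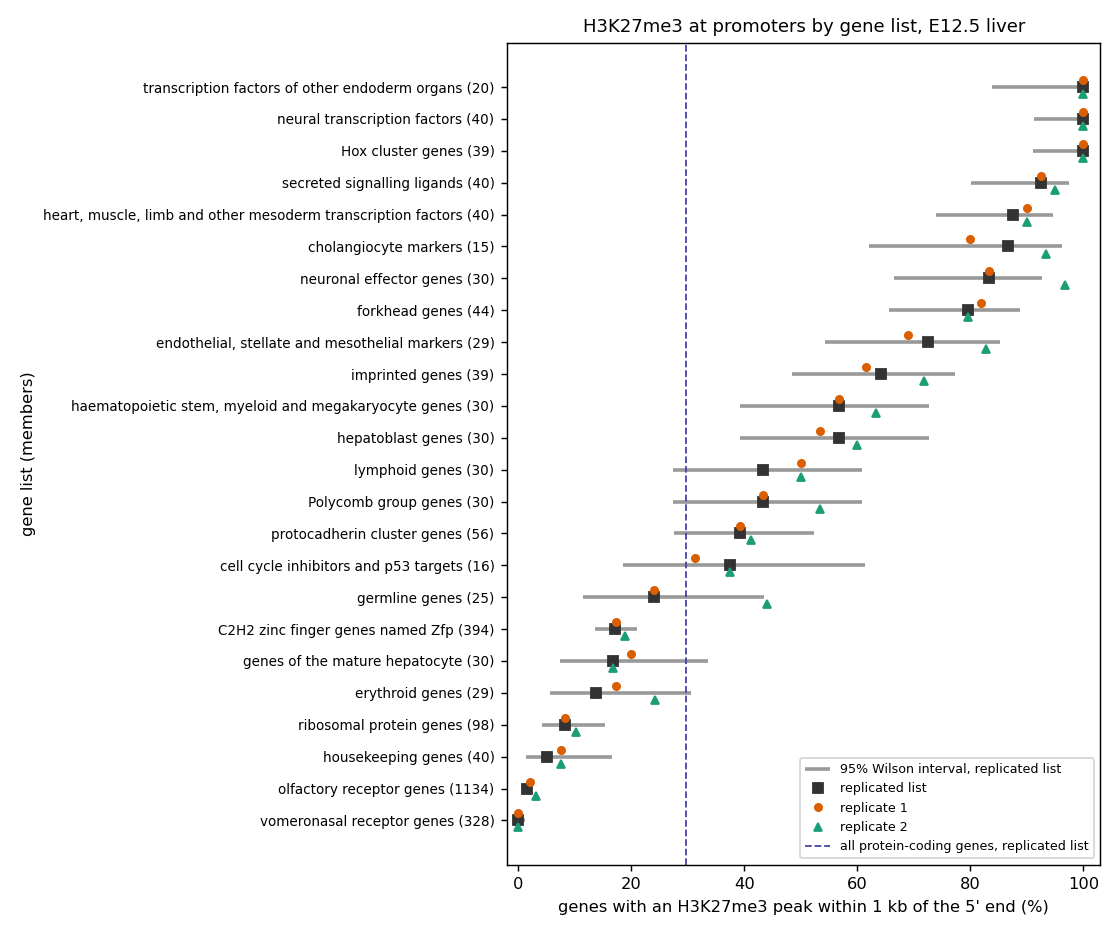
Share of each gene list with an H3K27me3 peak within 1 kb of the 5' end (x axis, %), for the replicated list (black squares with 95% Wilson intervals as grey lines), replicate 1 (orange circles) and replicate 2 (green triangles). Lists are on the y axis with their number of members, and the dashed line is the 29.7% of all protein-coding genes marked in the replicated list; 3 lists of transcription factors reach 100% and the vomeronasal receptors lie at 0%.

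Hepatoblast genes were marked more often than other genes, though some of the most typical ones had no peak near the 5' end. Of 30 hepatoblast genes, 17 were marked (56.7%, 95% Wilson interval 39.2 to 72.6), more than the 29.7% of other genes (adjusted p = 0.00316 by Fisher's exact test). Replicate 1 alone marked 16 and replicate 2 alone 18, or 56.7% ± 4.7 (SD, n = 2). The excess was uneven within the list. By a split chosen after the data were seen, 8 of 9 transcription factors and 9 of 21 other members were marked. Onecut1 and Onecut2, factors of hepatoblast and bile duct differentiation, Hhex, needed for liver bud growth, and Cebpa, a driver of hepatocyte differentiation, had 97.4% ± 3.7, 99.95% ± 0.071, 100% ± 0 and 100% ± 0 of the 5 kb around their 5' ends covered (SD, n = 2). Their highest signal values in the replicated list were 15.4, 22.5, 20.9 and 20.6. Alb and Afp, which encode albumin and alpha-fetoprotein, and the apolipoprotein genes Apoa2 and Apob had no peak within 2.5 kb of the 5' end in either replicate. Of the 30 genes of the mature hepatocyte, 5 were marked (16.7%, adjusted p = 0.175 by Fisher's exact test), namely the urea cycle gene Ass1, the glutaminase gene Gls2, the bile acid synthesis gene Cyp27a1, the tyrosine catabolism gene Hpd and the cytochrome gene Cyp1a2. Their mean covered shares over the replicates ran from 26.99% ± 4.0 at Cyp1a2 to 67.6% ± 13.6 at Ass1 (SD, n = 2). Of 15 markers of cholangiocytes, the bile duct cells that form later from hepatoblasts, 13 were marked (adjusted p = 1.43e-05 by Fisher's exact test). Hes1 and Jag1 of the Notch pathway, Sox9 and Hnf1b had means of 94.2% to 100% of the 5 kb covered.

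The lists of blood lineages were each tested against other genes and not against each other. Of 29 erythroid genes, 4 were marked (13.8%, 95% Wilson interval 5.50 to 30.6), which did not pass the test against other genes (adjusted p = 0.0898 by Fisher's exact test). The lists of replicates 1 and 2 alone marked 5 and 7 of them. The adult globin genes Hbb-bs and Hbb-bt had no peak within 2.5 kb of the 5' end in either replicate, and at Hba-a1 and Hba-a2 the covered share was 1.41% ± 2.0 and 3.41% ± 4.8 (SD, n = 2), with no peak in replicate 1. The marked members were the embryonic globin gene Hba-x (60.9% ± 3.8 of 5 kb), the red cell membrane skeleton genes Ank1 (99.5% ± 0.76) and Sptb (60.3% ± 22.7), and Trim58 (16.4% ± 1.8) (SD, n = 2 each). These shares are at the most upstream annotated start, which can lie away from the promoter that red cells use. With a promoter of 2.5 kb either side the erythroid share no longer lay below that of other genes (3.10 points above, adjusted p = 0.732 by Fisher's exact test). Of 30 genes of haematopoietic stem cells, myeloid cells and megakaryocytes, 17 were marked (adjusted p = 0.00316 by Fisher's exact test). Gata2 and Gfi1, regulators of blood stem and progenitor cells, the megakaryocyte and endothelial factor Fli1 and the platelet receptor gene Gp1bb had means of 99.3% to 100% of the 5 kb covered. Of 30 lymphoid genes, 13 were marked (43.3%, adjusted p = 0.134 by Fisher's exact test), among them the T cell factors Bcl11b, Tcf7 and Tbx21 and the B cell factor Pax5, with means of 99.0% to 100%. The lymphoid list passed the threshold in the pooled list (24.4 points above other genes, adjusted p = 0.00954 by Fisher's exact test), in the list of replicate 1 alone and with any transcript start. Of 29 endothelial, stellate and mesothelial markers, 21 were marked (adjusted p = 5.12e-06 by Fisher's exact test). Foxf1 and Lhx2, a factor of hepatic stellate cells, were fully covered in both replicates, and the endothelial genes Flt1 and Sox18 had means of 95.8% ± 2.0 and 99.2% ± 1.1 (SD, n = 2).

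**Figure D3:**
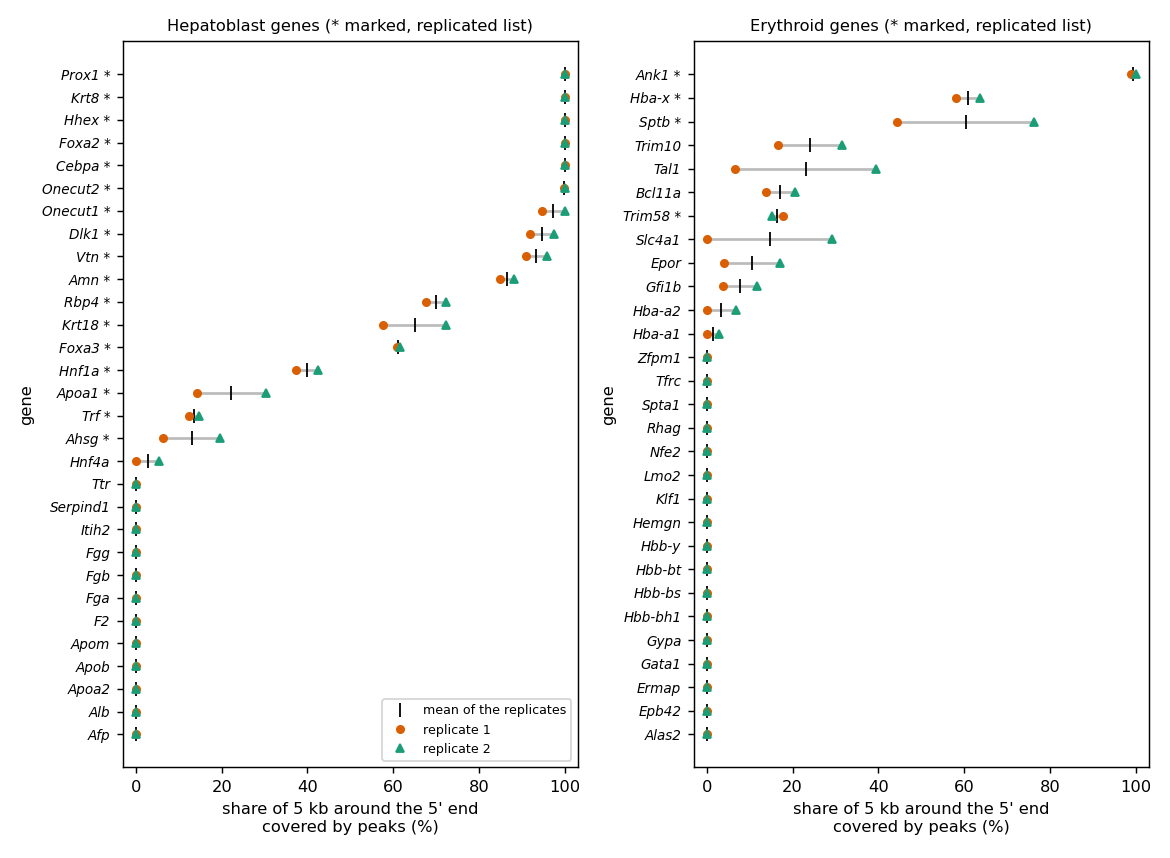
Share of the 5 kb around each gene's 5' end covered by peaks (x axis, %) in replicate 1 (orange circles) and replicate 2 (green triangles), with the mean as a black tick and a grey line joining the replicates, for 30 hepatoblast genes and 29 erythroid genes (y axis). Asterisks are genes marked in the replicated list, 17 and 4; Alb and Afp lie at 0% in both replicates.

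Signalling and neuronal genes were marked at high rates. Of 40 secreted ligands of the Wnt, hedgehog, fibroblast growth factor and bone morphogenetic protein families, 37 were marked (adjusted p = 5.15e-16 by Fisher's exact test), with Wnt3a, Wnt9a and Fgf3 fully covered in both replicates and Wnt7b at 98.8% ± 1.7 (SD, n = 2). The unmarked ligands were Fgf10, Fgf20 and Bmp5, named after their values were seen. Of 30 effector genes of differentiated neurons and glia, 25 were marked (adjusted p = 4.67e-09 by Fisher's exact test), including Slc32a1 and Gad2, which load and make the transmitter GABA, the neurofilament gene Nefm and the glutamate receptor gene Grin1. Of 39 imprinted genes, 25 were marked (64.1%, adjusted p = 1.76e-05 by Fisher's exact test). The thyroid hormone deiodinase gene Dio3 was fully covered in both replicates, and Phlda2, Grb10 and the placental factor Ascl2 had means of 96.9% to 99.6%. The peaks do not tell the parental alleles apart.

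The lists of cell cycle, Polycomb and germline genes did not pass the test against other genes. Of 16 cell cycle inhibitors and p53 targets, 6 were marked (adjusted p = 0.61 by Fisher's exact test), among them Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes, with 98.9% ± 1.5 and 80.3% ± 7.9 of the 5 kb covered (SD, n = 2), Gadd45b and Pmaip1. Of 30 Polycomb group genes, 13 were marked (adjusted p = 0.134 by Fisher's exact test), among them Cbx2, Cbx4, Cbx8 and Pcgf5, subunits of Polycomb repressive complex 1, with means of 97.9% to 100%. That list passed the threshold in the replicate 2 list alone (20.0 points above other genes, adjusted p = 0.0413 by Fisher's exact test) and with the promoter of 2.5 kb. Of 25 germline genes, 6 were marked (adjusted p = 0.664 by Fisher's exact test), with Tdrd1, Prm1, Figla and Ddx4 leading at means of 16.4% to 61.6%. Replicate 2 alone marked 11 germline genes, which put the list 10.7 points above other genes where the replicated list put it below.

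Housekeeping genes and large receptor families seldom had a peak at the promoter. Of 40 housekeeping genes, 2 were marked (5.0%, 95% Wilson interval 1.38 to 16.5, adjusted p = 2.93e-04 by Fisher's exact test), and 3 in each replicate's own list. The 2 were Eef1a1, an elongation factor gene, and Nono, an RNA-binding protein gene, with 8.45% ± 3.0 and 6.07% ± 3.1 of the 5 kb covered (SD, n = 2), and neither remained with a requirement that 25% of the promoter be covered. Actb, Gapdh, Hprt and Tbp had no peak within 2.5 kb of the 5' end in either replicate. Of 1134 olfactory receptor genes, 17 were marked (1.499%, adjusted p = 5.21e-147 by Fisher's exact test), led by Olfr750, Olfr71, Olfr222 and Olfr95 with means of 29.4% to 39.7% of the 5 kb covered. The lists of replicates 1 and 2 alone marked 24 and 35 of them (2.12% and 3.09%). None of 328 vomeronasal receptor genes was marked (95% Wilson upper limit 1.16%, adjusted p = 2.77e-50 by Fisher's exact test). These receptor genes lie in clusters, and with 1 member per locus 5 of 86 olfactory and 0 of 105 vomeronasal members were marked (adjusted p = 4.06e-08 and 7.16e-16 by Fisher's exact test). Of 394 zinc finger genes named Zfp, 67 were marked (17.0%, adjusted p = 1.36e-08 by Fisher's exact test), with Zfp503 and Zfp423 fully covered in both replicates and Zfp580 and Zfp536 at means of 99.2% and 99.0%. Of 44 forkhead genes, a family of developmental transcription factors, 35 were marked (adjusted p = 3.94e-11 by Fisher's exact test), among them Foxl2, Foxd2, Foxf1 and Foxc2. Of 56 genes of the protocadherin clusters, 22 were marked (adjusted p = 0.162 by Fisher's exact test), led by Pcdhga10, Pcdhgc4, Pcdhgb7 and Pcdhga11. Of 98 genes whose symbols follow the ribosomal protein pattern, 8 were marked (adjusted p = 7.07e-07 by Fisher's exact test). That pattern also took 10 genes of S6 kinases and their relatives, and 4 of the 8 marked genes, Rps6ka4, Rps6ka1, Rps6ka2 and Rps6kl1, were of this kind and not ribosomal proteins.

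With peaks joined up to 3 kb, 4 of the 5 longest H3K27me3 domains lay over the Hox clusters. Joining replicated peaks that lay within 3 kb of each other gave 25986 domains, of which 2904 were 10 kb or longer. The longest spanned 257 kb over the HoxC cluster, from Hoxc13 to Hoxc4 (GRCm38 chromosome 15, 102894720 to 103151890). The replicates' own peaks covered 88.2% ± 6.4 of it (SD, n = 2), 8.0% of it was exonic and 68.3% lay outside protein-coding genes. The HoxA domain with Evx1 spanned 192 kb (chromosome 6, 52136833 to 52328411; 84.9% ± 5.4 covered), the HoxB domain from Hoxb9 to Hoxb1 156 kb (chromosome 11, 96227444 to 96383271; 85.0% ± 6.2) and the HoxD domain with Evx2 134 kb (chromosome 2, 74639545 to 74773611; 89.3% ± 3.7) (SD, n = 2 each). Between them in length came a 145 kb domain on chromosome 7 (79480600 to 79626068; 77.0% ± 9.8 covered, SD, n = 2), where the only protein-coding gene was Rhcg, an ammonium transporter gene, beside Mir9-3hg, the host gene of a microRNA of neural development. The remaining domains among the 10 longest lay over Cacna1g with Abcc3, Spata20, Epn3 and Mycbpap (128 kb), the somite and neural factor gene Uncx (123 kb), the calcium channel subunit gene Cacna2d2 (112 kb), Cbx2 with Cbx8 and Cbx4 (110 kb) and Lhx2 (108 kb), with replicate means of 58.3% to 70.3% covered. The 5' ends of all 39 Hox genes and all 40 neural factors lay in domains of 10 kb or more, as did those of 10 of 30 hepatoblast genes, 1 of 29 erythroid genes and 2292 of all protein-coding genes (10.5%). The ranking depended on the joining distance. With peaks joined only up to 1 kb, 1667 domains reached 10 kb, and 5 of the 10 longest domains, the 4 Hox clusters and the one with Rhcg, were still among the 10 longest. Joined up to 10 kb, 4670 domains reached 10 kb, the longest spanned 556.8 kb, and only 2 of the 10, HoxC and HoxB, were still among the 10 longest.

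**Figure D4:**
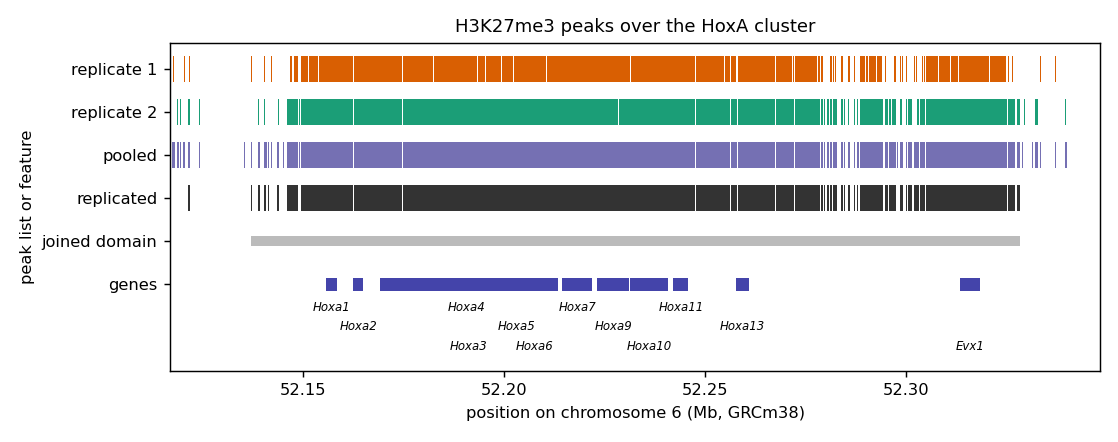
Map of the HoxA cluster on chromosome 6 (x axis, position in Mb, GRCm38) with the peaks of the replicate 1 (orange), replicate 2 (green), pooled (purple) and replicated (black) lists in rows, the joined domain as a grey bar and gene bodies in blue. The domain runs from 52136833 to 52328411, and the replicates' own peaks covered 84.9% ± 5.4 of it (SD, n = 2).

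Most of the highest signal values at promoters belonged to transcription factor genes. The highest was 30.3, in a peak of 13714 bp at Onecut3, a gene of the same family as Onecut1 (chromosome 10, 80488359 to 80502072), of which 9.89% was exonic, 42.9% intronic and 47.2% outside protein-coding genes. The own peaks of replicates 1 and 2 reached 23.6 and 31.4 there. Pou3f1, a neural POU factor, had a value of 30.3 in a peak that held the whole gene (chromosome 4, 124647634 to 124669755). Next came Olig2 at 29.2, the neural crest factor gene Tlx2 at 29.0, the pharyngeal factor gene Tbx1 at 28.7, Uncx at 28.6, and Hoxd11 and Hoxd12, which shared a peak at 28.4. Pcgf1 entered at 29.0 because the end of the Tlx2 peak reached its promoter; the replicates' own peaks there had values of 4.09 and 4.59. The only member of these 10 that encodes neither a transcription factor nor a Polycomb protein was the cartilage matrix gene Cilp2 at 28.2. The values are the authors' and rank peaks within a list only.

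Marked promoters were richer in CpG dinucleotides than unmarked ones. The median ratio of observed to expected CpG in 1 kb around the 5' end was 0.61 at marked and 0.48 at unmarked promoters (two-sided permutation p = 1e-05, the smallest that 100000 resamples allow). The mark was present at 3296 of 9725 promoters of CpG island class (33.9%) and at 3219 of 12186 others (26.4%), an odds ratio of 1.43 (Fisher's exact p = 3.54e-33). In the list of replicate 1 alone the odds ratio was 1.32. In that of replicate 2 alone it was 1.23, with 35.9% against 31.3% marked. Random gene lists matched on CpG content were marked at 29.8% for the hepatoblast list and at 37.7% for the Hox list, and every list called above kept its call against such matched lists. The size of some differences changed with matching: from -29.8 to -11.8 points for olfactory receptor genes, from -30.2 to -10.8 for vomeronasal receptor genes and from -13.0 to -20.4 for Zfp genes. The matched lists left out only the list's own members, so those for 1 receptor family could hold genes of the other. How far this lowered their marked share was not tested. The most upstream annotated start was used for each gene and can lie away from the CpG island of the promoter in use; only 6 of the 30 hepatoblast genes had a 5' end of CpG island class.

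Chromosome X held fewer marked bases than its length would give, though 1 autosome held fewer still for its length. Its share of the bases in replicated peaks was 0.604 of its share of the genome length, against a median of 1.13 and a range of 0.57 to 2.16 over the 19 autosomes. It ranked 19 of 20 chromosomes (two-sided rank permutation p = 0.2). The smallest p this rank test can give is 0.1, so no rank could pass 0.05 and the test decides nothing. In the replicate 1 and replicate 2 lists the ratios were 0.563 and 0.587, and X ranked lowest in both (permutation p = 0.1 in each). Counted in peaks the ratio was 0.908, and X ranked 12. Peaks on X were shorter, with a median length of 490 bp against 561.5 to 618 bp on the autosomes, and X ranked last in median length in the lists of both replicates as well. No list held a peak on chromosome Y.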

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

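The tests of signal from other cells, of all marked hepatoblast members, of the strongest 5% of replicate 2 peaks and their distance to replicate 1 peaks, of fewer reads on chromosome X, of the length of its peaks and of their number in each replicate's own list were chosen only after the results they concern were seen, as was the comparison of pooled peaks with random placement.

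Some peaks lay outside the replicated list or the assembled chromosomes, on which the main comparisons rest. The pooled list, used above only as an alternative, held 114349 peaks outside the replicated list, with a median length of 249 bp and a median signal value of 2.21, and 57.4% of them lay within 3 kb of a replicated peak, against 10.8% by random placement (one-sided permutation p = 0.0099, the smallest that 100 placements allow). Another 1303 protein-coding genes had a promoter overlapped by such peaks alone. On an unplaced scaffold, outside the assembled chromosomes, the replicated list held 1 peak of 581 bp with a signal value of 4.55, and each replicate's own list held 2 peaks there.

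Hepatoblast genes carried H3K27me3 in an organ that uses them, with 17 of 30 marked, namely 8 of 9 transcription factors and 9 of 21 other members. Lists matched on CpG content around the annotated 5' end were marked at 29.8% (adjusted p = 0.0036 by permutation), which argues against that content alone. These lists were not matched on the share of transcription factors. The most upstream annotated start can lie away from the CpG island of the promoter in use. The CpG content of that promoter therefore stays open. Signal from the blood cells of the organ, in which hepatoblast genes may be silenced, stays open: all 6 hepatoblast and 2 of 6 erythroid promoters of CpG island class were marked (Fisher's exact p = 0.0606), and over all members it was 17 of 30 against 4 of 29 (Fisher's exact p = 9.16e-04), a comparison that does not match promoter class. A mark in only part of the cells would lower the signal. The ratio of median signal values, hepatoblast over neural factors at CpG islands, was 0.956 (permutation p = 0.726). It was 0.881 and 0.870 in the lists of replicates 1 and 2. That decides nothing with 6 genes and a signal value whose reference is unknown. Over all marked members the ratio was 0.661 (permutation p = 3.8e-04), and 0.666 and 0.587 in the lists of replicates 1 and 2. That comparison does not match promoter class, so a mark in part of the cells stays open. Whether hepatoblasts themselves carry the mark cannot be told apart from signal of other cells in whole tissue, and no biological explanation was tested, as the design has 1 group.

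Replicate 2 had more peaks than replicate 1. The bound set beforehand for extra weak regions alone was not met. Of the strongest 25% of replicate 2 peaks, 26.8% lay outside replicate 1 peaks, where under 10% had been required. That 25% reached down to a −log10 p of 6.91. By a split chosen afterwards, 6.03% of the strongest 10% lay outside replicate 1 peaks, against 40.6% of the peaks from 10% to 25%. The bound therefore cannot decide, and extra weak regions stay open. The same 26.8% met the bound set for strong regions specific to the embryos of replicate 2, but of the strongest 5% of replicate 2 peaks 0.351% lay outside replicate 1 peaks and only 4.22% of the strongest 25% lay farther than 3 kb from one, so that explanation stays open. The lists also differ in the number of further files behind them, 1 for replicate 1 and 2 for replicate 2, which cannot be told apart from the replicates themselves. Depth, unknown for both, was not tested.

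Chromosome X carried shorter peaks than autosomes of similar gene density. The comparison of peak length was chosen when X was already known to rank last of 20 chromosomes in median length, so its outcome was largely known. The median length outside promoters was 476.5 bp on X against 534 to 553 bp on the 5 autosomes nearest in gene density. It was 260 against 271 to 275 bp in the list of replicate 1 and 265 against 273 to 287 bp in that of replicate 2. These autosomes thus did not share the short peaks of X in any of these lists, which argues against low gene density alone for the length of the peaks. For the number of peaks, low gene density alone stays open. X had 22.4 replicated peaks per Mb outside promoters against 13.1 to 20.6 on these autosomes, above their range. The bound set beforehand took such an excess as evidence against low gene density alone. In the replicates' own lists X lay within the range (29.4 against 20.0 to 29.5 per Mb, and 45.2 against 31.4 to 45.3), so the excess did not hold in every list. A low level of the mark along the chromosome, as on an inactive X in the female embryos, stays open: the share of X peaks outside promoters, 91.7%, was the highest of 20 chromosomes, though X ranked 4 and 2 in the lists of replicates 1 and 2. The median signal value of these peaks tied with the lowest autosome in the replicated list but was the highest of all chromosomes in each replicate's own list. Fewer reads on X, which male embryos hold in a single copy, could raise the signal a peak needs, and the median signal values of X peaks, 2.88 in both replicates, lay above the autosomal ranges, which end at 2.85 and 2.81. Fewer reads would not add peaks, and the number on X exceeded that of these 5 autosomes in the replicated list but not in the replicates' own lists, so this too stays open.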

How the results depend on the processing

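Marking in both replicates' own lists was an alternative chosen after seeing the data; the others were planned. Of 286 results under alternatives, 274 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. For chromosome X these labels rest on direction alone, since its rank test cannot pass the threshold. Marked genes ranged from 5723 to 7818. The calls of the Hox, neural, mesoderm, other endoderm, hepatoblast, cholangiocyte, stem and myeloid, endothelial, neuronal, ligand, imprinted, forkhead, housekeeping, olfactory, vomeronasal, Zfp and ribosomal lists held under every alternative run. In points above other genes, lymphoid genes became significant with the pooled list (24.4, adjusted p = 0.00954 by Fisher's exact test) and any transcript start (20.5), and lay between 16.7 and 20.4 with each replicate left out. Polycomb genes became significant with the wider promoter (21.9), and lay between 13.7 and 20.0 with each replicate left out. Germline genes turned from below to above other genes with the pooled list (16.3) and lay between -5.64 and 10.7 with each replicate left out, and erythroid genes turned with the wider promoter (3.10). The cause was not tested. Joining peaks up to 1 kb gave 1667 domains of 10 kb or more, and joining up to 10 kb gave 15872 domains, 4670 of 10 kb or more and a longest of 556.8 kb, with 5 and 2 of the 10 longest domains still among the 10 longest; the larger count follows from the joining rule. Leaving out a replicate gives no value for the replicate overlap, which needs both. Unknown depth limits all peak counts.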

Other observations

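The tests in these paragraphs were all chosen after the data were seen.

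Further gene families, grouped by the shared start of their symbols, also stood out among 242 families of at least 10 protein-coding genes, of which 44 were marked more often and 34 less often than other genes (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). Of 45 collagen genes, 34 were marked (adjusted p = 3.43e-08 by Fisher's exact test), and of 20 semaphorin genes, which guide axons and vessels, 19 were (adjusted p = 1.12e-07). Synaptotagmin genes, which serve vesicle release, were marked at 16 of 17, serotonin receptor genes at 13 of 14, frizzled genes for Wnt receptors at 9 of 10, and solute carrier genes at 161 of 371. Histone genes named Hist were marked at 1 of 67 (adjusted p = 1.68e-07 by Fisher's exact test), and the Rhox homeobox genes, expressed in the reproductive tract, at 0 of 34 (adjusted p = 1.56e-04). Within the protocadherins, 0 of 22 genes of the beta cluster (adjusted p = 0.00431 by Fisher's exact test) and 0 of 11 alpha genes with a number after Pcdha (adjusted p = 0.0897) were marked. Of the 22 marked cluster genes, 20 lay in the gamma cluster, which has 21 in all, and the others were Pcdhac1 and Pcdhac2 of the alpha cluster, while all 12 protocadherins with a number after the shared root were marked (adjusted p = 1.27e-05 by Fisher's exact test). Members of a cluster share regions and are not independent.

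Long non-coding RNA genes carried the mark too. Of 7857 whose 5' end lay more than 5 kb from any protein-coding 5' end, 1174 had a replicated peak within 1 kb (14.9%). The shares were 15.7% and 20.6% in the lists of replicates 1 and 2. The 14.9% was below the 29.7% of protein-coding genes (Fisher's exact p = 2.59e-157). Protein-coding genes were not held to that distance, and the sets were not matched on CpG content. Over all 10155 long non-coding RNA genes the share was 20.8%. Hotair in the HoxC cluster and Mir9-3hg had 98.2% and 100% of the surrounding 5 kb covered in replicate 1 and 100% of both in replicate 2. The imprinted Meg3 had 48.9% and 65.3% covered in replicates 1 and 2 and H19 had 0% and 25.2%, while Xist, Airn and Kcnq1ot1 had 0% in both. Among hepatoblast genes, 8 of 9 transcription factors were marked, Hnf4a being the exception, against 9 of 21 other members (Fisher's exact p = 0.0417, unadjusted).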
